A study of Mus musculus with 2 samples.

How the data were processed

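STAT5 CUT&Tag was carried out on primary mouse aortic valve interstitial cells after 7 days of osteogenic treatment, with 1 library from Tert wild-type cells and 1 from Tert knockout cells, per the labels. The libraries were made with a commercial CUT&Tag kit and 14 PCR cycles, per the labels' protocols. The authors called peaks per library, with 1 deposited list for each. Coordinates are on mm10, per the submitters' processing notes. The aligner, the peak caller, the gene annotation release, the treatment of duplicate reads, the use of a control library and the read depth were not given in the sources used here.

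For each peak the authors deposited a position, a width in bp, a peak shape score and a p-value, together with the neighbouring gene on the lower and the higher coordinate side and the distance to it, per the file headers. The score deposited by the authors measures how well a peak resembles a peak shape, per the file headers, and has no fixed range. The deposited p-value was checked against the upper tail of a standard normal distribution at the score and differed from it by less than 1e-06 in every peak of both lists, so score and p-value give the same ranking and the p-value is not adjusted for multiple testing. The deposited lists reached p-values of 0.199 in the wild type and 0.1999 in the knockout, so they include many weak peaks. Positions count from 1 and include both ends, as width equalled end minus start plus 1 in all 1217 and 837 peaks. Scores were used to rank and filter peaks within a list. The numbers of peaks past the same p-value or score in each list are also given, as a description, since it is unknown whether scores of separate lists are on the same scale. Read counts per peak were not used here, and differences in depth or duplicate content could change the number, width and score of the peaks.

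A peak was assigned to the genes it overlapped by the authors' columns (a distance of 0), and otherwise to the nearer neighbour. Gene names were matched to a RefSeq table of GRCm38.p6, the assembly that mm10 represents, by symbol and synonym, and 86.2% of the wild-type and 84.8% of the knockout gene names matched. Computed distances to matched genes were within 2 bp of the deposited ones in 52.3% and 51.4% of cases and within 5000 bp in 96.1% and 95.9%, so the same build was used for gene extents. The table gave gene extents without exons, strands or transcription start sites. Promoter, exon, intron and UTR shares were therefore not analysed here, and gene bodies and gene ends took their place. The planned count of STAT5 motifs in peaks was not run, since no genome sequence was used here.

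Peaks were called shared when they overlapped by at least 1 bp, computed in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) and checked with bedtools 2.31.1, which gave the same numbers. As a background, the peaks of both lists were placed at random 1000 times on their own chromosomes between the first and the last RefSeq gene, and 200 times for shared genes and for clusters. A cluster was 3 or more nuclear peaks with gaps of at most 5000 bp. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, and a count of 0 was read as allowing up to 3 counts unless an exact interval is named. The 22 gene lists of 468 genes were fixed before the data were examined, as were the main comparisons and some of the other settings tried. Each list's number of members with a peak was set beside 10000 random lists of the same size drawn from 21884 genes in the same 10 classes of gene length. The overlap step was tested on simulated lists with 100 planted shared positions among 1181 peaks, of which 100 were found with 0 others. The planted positions were identical intervals in both lists, unlike the real peaks, which differed in width. On simulated lists the gene list step called 4 of 100 random lists and 100 of 100 lists with 10 of 25 members planted. Smaller excesses were not simulated, and simulated hits were drawn without regard to gene length, so the matching on length was not tested. No test was made between the libraries, and no p-value of the re-analysis is given.

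Genes were named by a rule set beforehand. Tert, Stat5a, Stat5b, Runx2, Cish, Socs2, Bcl2l1 and Bcl6 were always named, followed by the genes of the 10 highest-scoring peaks in each library, those of the 10 highest-scoring peaks that overlap no peak of the other library, and up to 4 members of each list with a peak, taking those in 1 library alone first. Gene models without a symbol were passed over for the next rank. Wnt5b, Wnt7b, Gsk3b, Tcf7l1 and Acvr2a, the neighbours Ghdc and Stat3, the positions beside D430019H16Rik and Pak3, and the clusters and chromosome-end peaks of the closing section were named after their values were seen. Alternatives changed the peaks kept, the overlap required, the gene assignment and the matching of random lists. The members of the neuron and photoreceptor list with a knockout peak are not reported here by name. Plots were drawn with matplotlib 3.10.9.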

Results

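Binding of the transcription factor STAT5 was profiled by CUT&Tag, in which an antibody directs a DNA-cutting transposase to the chromatin that carries the target protein, in primary mouse aortic valve interstitial cells, the fibroblast-like cells of the heart valve. The cells had spent 7 days in a medium that drives them toward a bone-like state, which contained dexamethasone at 100 nM, glycerol phosphate at 10 mM and a stable form of ascorbic acid at 50 µM. There were 2 groups with 1 library each, from cells with intact Tert, the gene of the telomerase catalytic subunit, and from Tert knockout cells. The deposited lists held 1217 peaks for the wild type and 837 for the knockout. Read depth was not given in the sources used here, so it is unknown how far depth sets these numbers, and with 1 library per genotype no difference between the genotypes had a replicate check. The series title names telomerase reverse transcriptase, osteogenic reprogramming and STAT5, and the question addressed by the comparison was where STAT5 lay on the genome with and without TERT. The score and p-value quoted for a peak are the authors' own, not adjusted for multiple testing, and they rank peaks within 1 list.

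Tert itself carried 3 peaks in the wild-type list and 0 in the knockout list. The Tert peaks lay inside the gene body (chromosome 13, 73626911 to 73649843, mm10), at 73627076 to 73627163 with a score of 2.38, at 73642016 to 73642102 with a score of 2.09, and at 73644251 to 73644333 with a score of 2.48. Their p-values were 0.00865, 0.0182 and 0.00654. The knockout list had few peaks of such p-values anywhere, with 40 under 0.05 against 393 in the wild type. A count of 0 also allows up to 3, so 3 against 0 does not show a difference between the genotypes at Tert. A list of peaks does not measure whether the gene is present, so these peaks did not test the genotype labels.

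Stat5a and Stat5b, the neighbouring genes that encode the STAT5 proteins, carried repeated peaks in both libraries. The Stat5a gene body (chromosome 11, 100859351 to 100885169) held 15 wild-type peaks and 5 knockout peaks, and the Stat5b gene body (100780731 to 100859004) held 9 and 3. In the wild type, 14 of the 15 Stat5a peaks had a p-value under 0.05 and their scores ran from 1.05 to 4.83, the highest at 100876972 to 100877052. The 5 knockout peaks of Stat5a had p-values from 0.0865 to 0.176, and all 5 overlapped a wild-type peak. In Stat5b, 7 of the 9 wild-type peaks had a p-value under 0.05, the highest score being 4.56 at 100804892 to 100804974, and the 3 knockout peaks had p-values from 0.164 to 0.176, 2 of them overlapping a wild-type peak. The Stat5b peaks of the wild type fell within 14.2 kb of the 78.3 kb gene and left a stretch of 54.0 kb of its body without a peak. Between the neighbouring genes Ghdc and Stat3 the 11.7 kb outside the 2 gene bodies held 0 peaks in both lists, and Stat3, which encodes a related STAT protein, also held 0.

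**Figure D1:**
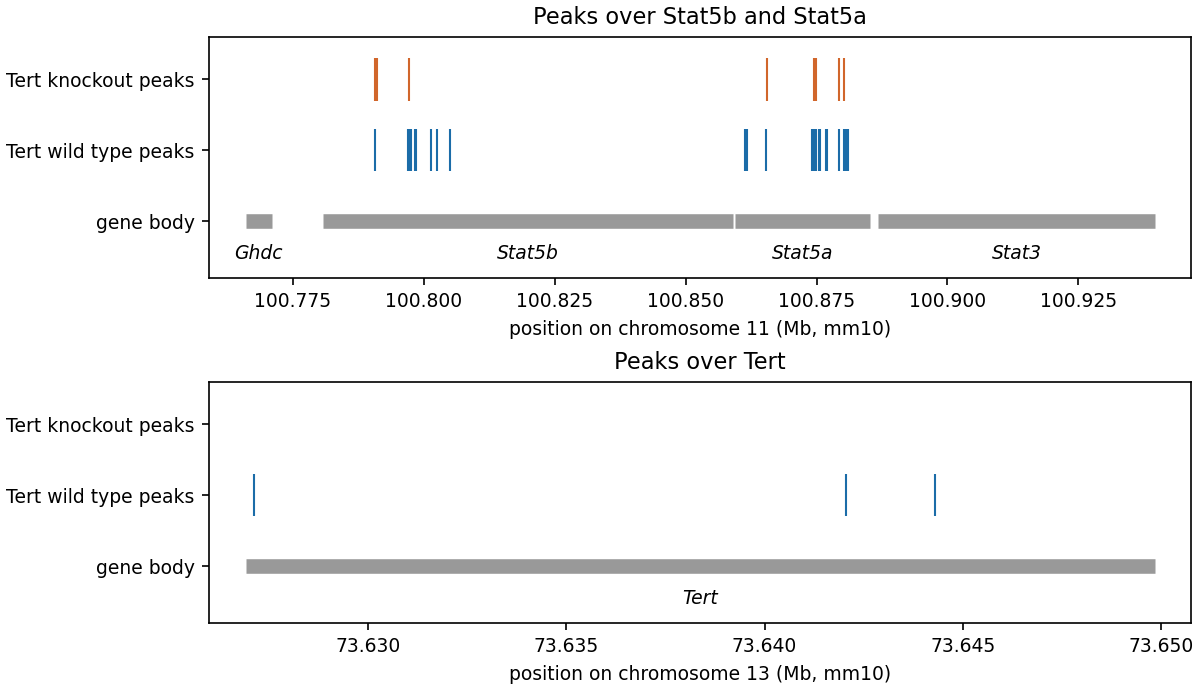
Positions of peak centres (vertical ticks) of the wild-type and knockout libraries along chromosome 11 over Stat5b and Stat5a and along chromosome 13 over Tert, in Mb of mm10, with grey bars for the gene bodies. The ticks show 9 wild-type and 3 knockout peaks in Stat5b, 15 and 5 in Stat5a, and 3 and 0 in Tert.

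Known STAT5 target genes mostly lacked a peak in both genotypes. Cish and Socs2, cytokine-induced inhibitors of the pathway, and Bcl2l1, an anti-apoptotic gene, were assigned no peak in either list, and neither was Runx2, the master transcription factor of bone formation. Bcl6, a transcriptional repressor and STAT5 target, had a peak in the knockout alone (chromosome 16, 23966306 to 23966571), inside the gene body, with a score of 0.993 and a p-value of 0.160. Myc was the nearest gene of a wild-type peak 203107 bp away (chromosome 15, 62193482 to 62193561, p-value 0.0388) and of a knockout peak 439751 bp away (62430126 to 62430464, p-value 0.170), at separate positions. Of the 25 genes in the fixed list of STAT5 targets, 1 was assigned a wild-type peak and 2 a knockout peak, against means of 1.11 and 0.739 in random lists matched on gene length. Of the 33 JAK and STAT pathway components, 2 carried a wild-type peak and 3 a knockout peak, namely Stat5a and Stat5b in both and Pias2, an inhibitor of activated STATs, in the knockout alone (random means 1.98 and 1.35).

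The wild-type list held more peaks than the knockout list, and the gap was widest among high-scoring peaks. The ratio of wild-type to knockout peaks was 1.45 over all peaks, 9.83 over peaks with a p-value under 0.05 (393 and 40) and 17.3 over those with a p-value under 0.01 (225 and 13). Peaks with a p-value under 0.05 made up 32.3% of the wild-type list (exact 95% interval 29.7 to 35.0) and 4.78% of the knockout list (3.44 to 6.45). Mitochondrial DNA carried 36 wild-type and 20 knockout peaks. Of the peaks with a p-value under 0.01 it took 21 of 225 in the wild type and 8 of 13 in the knockout. That left 204 nuclear wild-type and 5 nuclear knockout peaks under this limit. These nuclear numbers include peaks of 2 clusters described in the closing section. One, in the wild type, lay at a nuclear copy of mitochondrial DNA, and the other, in the knockout, beside Gm10800 and Gm10801. The peaks also differed in width, with a mean of 84.8 bp ± 5.94 (SD over 1217 peaks) in the wild type and 239 bp ± 46.6 (SD over 837 peaks) in the knockout, so the shorter knockout list covered 200 kb and the wild-type list 103 kb. How scores were set in each list was not given in the sources used here, so these numbers describe the lists and do not measure the strength of binding.

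**Figure D2:**
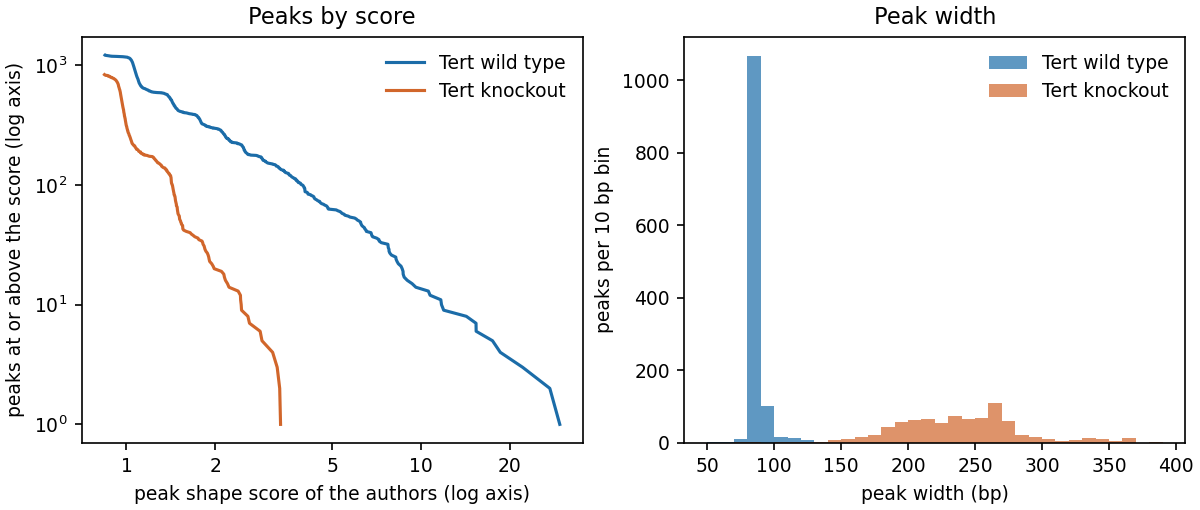
Left, the number of peaks at or above each score (both axes logarithmic) and right, the number of peaks per 10 bp bin of peak width, for the wild-type and knockout libraries. Wild-type scores reach 29.6 and knockout scores 3.34, and the median widths are 84 bp and 239 bp.

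The 10 highest-scoring wild-type peaks with a named gene were assigned to genes of varied function, often from a long distance. None of the 10 overlapped a knockout peak. The top score, 29.6, belonged to a peak 367941 bp from Arid1b, a chromatin remodelling subunit (chromosome 17, 4626289 to 4626390). It was followed among named genes by a peak inside Dpp9, a dipeptidyl peptidase (chromosome 17, 56200005 to 56200085, score 22.2), by a peak 14704 bp from Pla2r1, a phospholipase receptor (chromosome 2, 60402759 to 60402838, score 17.5), and by a peak 47423 bp from Sulf1, a heparan sulfate sulfatase (chromosome 1, 12644772 to 12644853, score 15.4). Peaks assigned to Nxph1, Olfr855, Ano2, Sh2d4b, Cldn34c1 and Acacb completed the 10, with scores from 15.4 down to 9.61. Those in Ano2, a chloride channel, and Acacb, an acetyl-CoA carboxylase, lay inside the gene. The others lay 937348 bp from Nxph1, 7098 bp from Olfr855, 128860 bp from Sh2d4b and 272031 bp from Cldn34c1.

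The highest-scoring knockout peaks with a named gene were on mitochondrial DNA, over mt-Nd2, mt-Co1, mt-Nd1 and mt-Nd5 and beside mt-Cytb, with scores from 3.25 down to 2.62. The nuclear peaks next in rank were 2968 bp from Nub1, a regulator of the ubiquitin-like protein NEDD8 (chromosome 5, 24682227 to 24682563, score 2.58), inside Fam155a (chromosome 8, 9495745 to 9496083, score 2.23), 1514664 bp from Cdh2, which encodes N-cadherin (chromosome 18, 18323911 to 18324228, score 2.17), inside Nckap5 (score 2.15) and 295 bp from the olfactory receptor gene Olfr459 (score 1.99). Leaving out positions shared with the wild type added Hdac9, a histone deacetylase (score 1.97, inside the gene), and Ebf2, a transcription factor (score 1.95, 102896 bp away). None of these nuclear peaks overlapped a wild-type peak.

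Outside mitochondrial DNA and the STAT5 genes, the genotypes shared almost no peak positions. Over all peaks, 23 wild-type peaks (1.89%, exact 95% interval 1.20 to 2.82) and 19 knockout peaks (2.27%, 1.37 to 3.52) overlapped a peak of the other list by at least 1 bp. On mitochondrial DNA 12 of 36 wild-type peaks and 10 of 20 knockout peaks were shared, against means of 12.3 and 10.4 in 1000 random placements on the same chromosome. Of the 11 shared nuclear peaks of the wild type, 9 lay in Stat5a or Stat5b, and random placement gave a mean of 0.136 shared nuclear peaks. The remaining pair of positions lay 31631 bp from the gene model D430019H16Rik (chromosome 12, 105524727 to 105524846) and 35493 bp from Pak3, a neuronal kinase gene (chromosome X, 143483018 to 143483097), with wild-type p-values of 0.0893 and 0.165. At the same places the knockout p-values were 0.178 and 0.158.

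The shared peaks of high rank were those of mitochondrial DNA and the STAT5 genes. In the top quartile by score 4.26% of wild-type peaks were shared (13 of 305, exact 95% interval 2.29 to 7.18) and in the lowest quartile 0.658% (0.0798 to 2.36). The knockout list gave 5.71% (2.99 to 9.77) and 1.44% (0.297 to 4.14). The intervals of the quartiles overlapped in both lists, in the wild type only narrowly, and overlap does not show that the shares are equal. Of the 12 shared knockout peaks in the top quartile, 10 were mitochondrial, all at rank 134 or better. Sharing on mitochondrial DNA was near its random mean (10 of 20 knockout peaks against 10.4), so the higher share at the top of the knockout list is not evidence of common binding sites. For nuclear peaks outside Stat5a and Stat5b the top quartile of the wild type held 0 shared peaks of 290, which allows a share of up to 1.26% (exact 95% interval), and the lowest quartile 1 of 289. Across the 23 overlapping pairs the scores had a Spearman correlation of -0.12, with 0.19 over the 11 nuclear and 0.29 over the 12 mitochondrial pairs, given as a description because peaks are not replicates.

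Peaks were spread over gene bodies and intergenic sequence in both genotypes, and the intervals of their shares inside genes overlapped. By the authors' gene columns 45.4% of nuclear wild-type peaks (exact 95% interval 42.5 to 48.3) and 41.4% of knockout peaks (38.0 to 44.8) overlapped a gene, and 24.5% and 29.7% lay over 50000 bp from the nearer gene. Over protein-coding RefSeq genes the wild-type share inside a gene was 47.2%, above the 95% range of random placement (37.3 to 42.7), and the knockout share was 43.8%, just above its random range (36.7 to 43.3). These shares include the 24 wild-type and 8 knockout peaks inside Stat5a and Stat5b. The shares without those peaks were not computed, so the small knockout excess may rest on them. Within 3000 bp of either end of a gene lay 10.9% of wild-type peaks (random range 6.69 to 9.82) and 8.94% of knockout peaks (6.36 to 10.3). Within 1000 bp both lists, at 3.81% and 3.30%, were inside the random range. Gene starts were not separated from gene ends, and random positions could fall in sequence to which reads do not map.

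The genotypes shared few genes as well. By the authors' columns 1073 genes were assigned a wild-type peak, 766 a knockout peak and 104 both, so 969 were assigned in the wild type alone and 662 in the knockout alone. With the nearest protein-coding RefSeq gene the numbers were 1041, 746 and 107. Random placement of both lists gave 147 genes in both (95% range 127 to 166), more than were observed. Random positions were spread evenly along each chromosome. Fewer of them fell inside genes (means of 40.0% for the wild type and 40.2% for the knockout) than of the peaks (47.2% and 43.8%). The background therefore differed from the lists, and the lower number cannot be read as the genotypes avoiding each other's genes.

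Among signalling groups, Wnt pathway genes carried more wild-type peaks than length-matched random lists. Of 30 Wnt genes, 7 were assigned a wild-type peak against a random mean of 1.87, and 0.15% of 10000 random lists reached as many. The members were Wnt5b, a ligand (score 2.47, p-value 0.00672, inside the gene), Sfrp1, a secreted antagonist (score 1.76, p-value 0.0392, 47372 bp away), Lrp5, a co-receptor, and Rspo2, Gsk3b, Tcf7l1 and Wnt7b, these 5 with p-values from 0.140 to 0.146. In the knockout 2 Wnt genes had a peak, Wnt5b at another position and Tcf7l2, against a random mean of 1.32. This was the 1 list above the 95% range of its random lists among 44 comparisons of 22 lists in 2 libraries, where up to 1.10 would lie there by chance, and with peaks of p-value under 0.05 alone 2 Wnt genes remained in the wild type, 9.58% of random lists reaching as many.

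BMP and TGF-beta genes, which govern bone and matrix formation, had 5 of 30 members with a wild-type peak and 2 with a knockout peak (random means 2.11 and 1.45). Smad4, Tgfbr1, Tgfbr2 and the antagonist Chrd were 4 of them, with wild-type p-values from 0.138 to 0.149. Their wild-type peaks lay 14978, 21541, 79603 and 14079 bp away, in that order, and Acvr2a lay 1137907 bp from its wild-type peak. When only genes within 5000 bp of a peak were assigned, 0 of 30 had a wild-type peak and 1 a knockout peak (random means 1.39 and 0.904). Of 30 osteogenic genes 2 had a wild-type peak, Phex, an endopeptidase needed for bone mineral, inside the gene (chromosome X, 157251640 to 157251722, p-value 0.133), and Fosl2, an AP-1 factor, at 262 bp (p-value 0.156). The knockout had 0 of 30, against a random mean of 0.898, so a lower number was not detectable at this size. Among 18 mineral metabolism genes 3 had a wild-type peak and 2 a knockout peak (random means 0.836 and 0.548). Of these Nt5e, which generates adenosine from AMP, had a wild-type peak inside the gene (score 1.80, p-value 0.0362) and a knockout peak 21825 bp away, Ankh, a pyrophosphate transporter, had peaks outside the gene in both, and Vdr, the vitamin D receptor, had a peak inside the gene in the wild type alone (p-value 0.141). The 14 chondrogenic genes gave 2 in each library (random means 0.804 and 0.564). In the wild type these were Hapln1, a cartilage link protein (chromosome 13, 89570597 to 89570681, score 3.96, p-value 3.74e-05), and Sox5, both with the peak inside the gene. In the knockout Sox9 had peaks 87600 and 218918 bp away and Col11a1 a peak 223380 bp away. When only genes within 5000 bp of a peak were assigned, the wild type kept 2 of 14 and the knockout 0 (random means 0.508 and 0.335). Notch genes gave 1 of 17 in the wild type, Jag1 (p-value 0.0360, 27898 bp away), and 0 in the knockout (random means 0.885 and 0.580).

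Groups that mark valve cells and their activated states stayed within the range of their random lists in both genotypes. Of 26 fibroblast and valve matrix genes, Col3a1 alone was assigned a wild-type peak, 255413 bp away. Col5a1 (inside the gene) and Tnc (450749 bp away) were assigned a knockout peak (random means 1.58 and 1.07). Of the 15 myofibroblast and smooth muscle genes measured, and of the 10 adipogenic genes, 0 had a peak in either library (random means 0.722 and 0.481, and 0.503 and 0.353). Glucocorticoid response genes, of interest because the medium held dexamethasone, gave Klf9 in the wild type (2468 bp away, p-value 0.142) and Sgk1 in the knockout (p-value 0.189), each 1 of 20 (random means 0.956 and 0.654). Telomere and telomerase genes gave Tert in the wild type and Stn1, a telomere capping subunit, in the knockout, each 1 of 19 (random means 0.647 and 0.454). Senescence and secretory genes gave 0 and 1 of 21 (Igfbp7, 694458 bp away), against random means of 0.606 and 0.365. Inflammation genes gave 2 (Il1r1, Ptgs2) and 1 (Tlr4) of 21, against 0.646 and 0.392, cell cycle genes 2 (Mcm5, Bub1) and 1 (Mcm6) of 24, against 0.817 and 0.517, and housekeeping genes 2 (Actb, Eif4a2) and 0 of 40, against 0.821 and 0.495.

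Markers of other cell types that a valve culture could hold also stayed within the range of their random lists. Endothelial genes gave 3 of 15 in the wild type, against a random mean of 0.999, with 7.05% of random lists reaching as many (2.34% without matching on gene length). Of these Vwf, the von Willebrand factor gene, had a peak inside the gene (chromosome 6, 125618010 to 125618095, score 3.56, p-value 0.000183), while Flt1 and Pecam1 had p-values of 0.138 and 0.141. The knockout had 0 of 15, against a random mean of 0.698. Macrophage and leukocyte genes gave C1qa in the wild type and Adgre1 in the knockout, each 1 of 16 (random means 0.695 and 0.459), and cardiomyocyte genes gave Ryr2 in the wild type and 0 of 15 in the knockout (0.572 and 0.405). Melanocyte and neural crest genes gave Tyrp1 and Mitf, each 1 of 10 (0.512 and 0.334). Neuron and photoreceptor genes, included as a background, gave 1 of 20 in the wild type (Gria1, 412104 bp away) and 3 in the knockout, against random means of 1.44 and 0.990. All lists except the Wnt list in the wild type had no more members with a peak than the upper end of the 95% range of random lists.

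**Figure D3:**
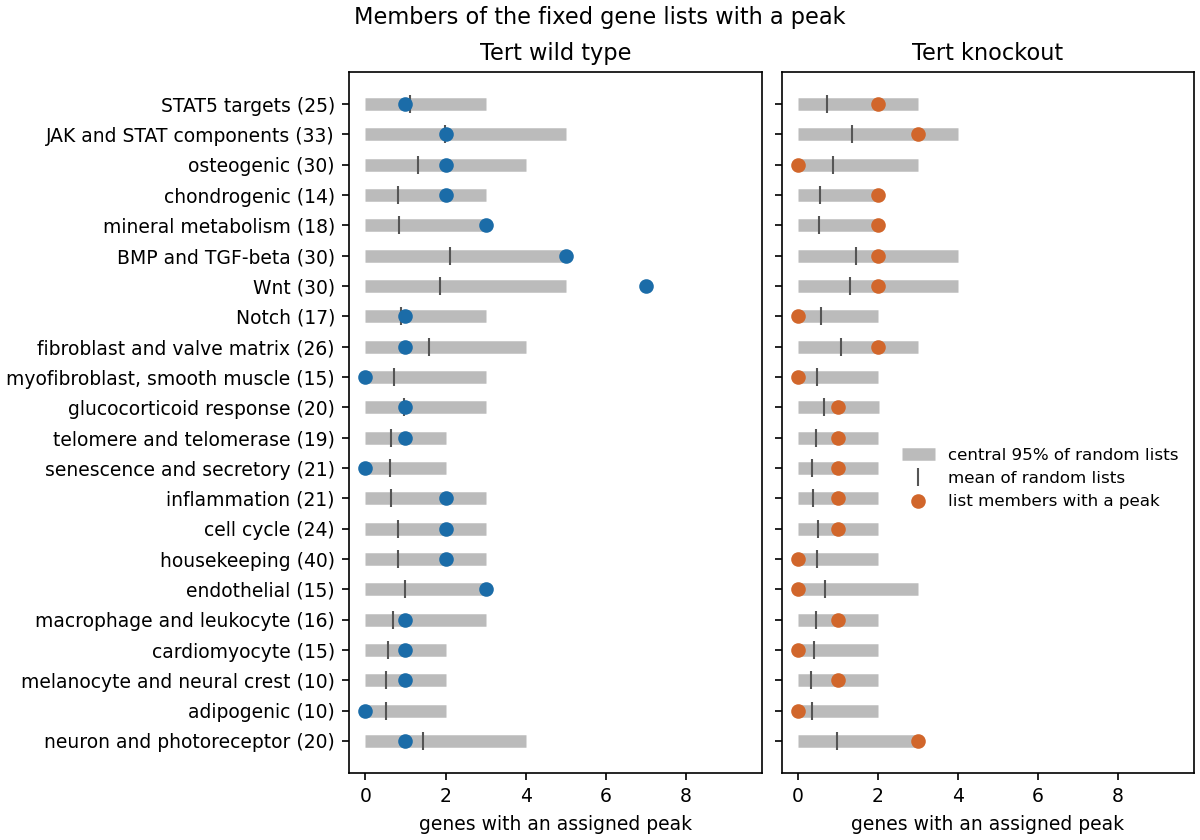
Members of each fixed gene list that were assigned a peak (points) in the wild-type and knockout libraries, with the mean (tick) and central 95% range (grey bar) of 10000 random lists matched on gene length; the number of genes measured follows each name. The wild-type Wnt point, at 7, lies right of its grey bar, and all other points lie on their bars.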

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

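Alternatives using a p-value limit, leaving out mitochondrial DNA and the STAT5 genes, using a window around the peak centre, changing the gene assignment, or matching random lists on territory (a gene with the nearer parts of its flanking gaps) were chosen after the data were seen, and the others before. Of the main results under all alternatives, 28 values stayed within their limit, which was 1.5 times the main value for numbers of peaks, genes and lists and the exact 95% interval for shares, and 40 moved beyond it. Counts and shares cannot change sign, so a reversal was not assessed for single values. The order of the libraries did change in places. With the longer list cut to the length of the shorter, genes with a peak numbered 732 in the wild type and 766 in the knockout. The shared shares were then 2.51% and 2.15%. A p-value limit of 0.05 left 393 wild-type and 40 knockout peaks (ratio 9.83), shared shares of 1.02% and 10.0%, 325, 31 and 5 genes (wild type, knockout, both), 50.0% of nuclear knockout peaks in gene bodies and 0 wild-type gene lists above their random lists, and a limit of 0.01 left 225 and 13 peaks (ratio 17.3). The higher-scoring part of each list (608 and 418 peaks) gave 522, 396 and 31 genes and 0 wild-type lists, and the wild-type list shortened to 837 peaks also gave 0 lists. The shared shares of wild type and knockout were 0.881% and 1.02% on chromosomes 1 to 19, 0% and 0% with a reciprocal overlap of 0.5 (0% and 0% in the top quartiles; at median widths of 84 and 239 bp a typical pair cannot meet this wherever it lies, so it says nothing about shared positions), 4.35% and 3.94% with peaks extended by 500 bp, 0.793% and 1.11% with peaks within 1000 bp merged, and 0.173% and 0.247% without mitochondrial DNA and the STAT5 genes, and the wild-type share was 2.88% with windows of 120 bp on each side of the centre. Genes within 5000 bp numbered 596, 383 and 27 and gave 1 knockout list, the neuron and photoreceptor list, while both neighbours gave 2000, 1459 and 266 genes. Unmatched random lists put 3 wild-type lists (Wnt, BMP and TGF-beta, endothelial) and 1 knockout list (neuron and photoreceptor) above. Fewer peaks or genes enter under the filters by construction; the cause of the other shifts was not tested. The 8 settings chosen beforehand but not run were a q-value of 0.01, distances to a transcription start site (5000 bp for genes and for lists, 3000 bp for promoters), 3 motif settings, and ranking by the other peak value, which orders peaks as the score does. No paired analysis was possible because each genotype had 1 library. Depth was unknown, so its effect on any of these numbers could not be measured.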

Other observations

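The tests below on the STAT5 genes and on chromosome ends were chosen only after the result was seen. So were the counts of clusters, chromosome-end peaks and small RNA genes. The predictions on shared positions were set before their result was seen. The peaks they cover, outside mitochondrial DNA and the STAT5 genes, were chosen after the data were seen. Some high-scoring wild-type peaks lay beyond the last gene of a chromosome and over high-copy RNA genes, for which no chance expectation was computed. Beyond the last gene of a chromosome lay 23 wild-type peaks (1.95% of 1181 nuclear peaks, exact 95% interval 1.24 to 2.91) on 14 chromosomes, and 0 of 817 knockout peaks, which allows a share of up to 0.367%. At the other end, before the first gene of a chromosome, lay 1 wild-type and 2 knockout peaks. Of the 23 beyond the last gene, 18 had a p-value under 0.01, and the highest scores were 7.94 and 7.79 on chromosome 7 (145340967 to 145341086 and 145341178 to 145341297), beyond the sensory receptor gene Mrgprd. Chromosome 14 carried 4 such peaks between 124801590 and 124802220. The genes Rn7s1 and Rn7s2, which encode the 7SL RNA of the signal recognition particle, each carried 2 wild-type peaks, with scores of 6.45 and 8.77 and of 8.70 and 6.08, and 0 knockout peaks.

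Clusters of 3 or more nuclear peaks numbered 8 in the wild type and 2 in the knockout, against random means of 0.01 and 0. The wild-type cluster with 10 peaks on chromosome 1 (24611816 to 24616169) overlapped the pseudogenes Gm10222 and Gm10925, at a site known to hold a nuclear copy of mitochondrial DNA, and 0 knockout peaks lay in it. A cluster of 5 lay inside Myo3a, a myosin gene (chromosome 2, 22588054 to 22589862, top score 8.64), and one of 3 at 829258 bp or more from Tyrp1 (chromosome 4, 80002445 to 80004864). The knockout clusters were 4 peaks in Stat5a and 5 at 98662225 to 98667259 on chromosome 2, beside Gm10800 and Gm10801, which held its top score of 3.34 and 0 wild-type peaks.

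The repeated peaks over Stat5a and Stat5b in both lists are the pattern most in need of follow-up. They formed clusters over both genes in the wild type and over Stat5a alone in the knockout. STAT5 occupying its known target genes, its own genes among them, stays open, since 1 of 25 STAT5 targets had a wild-type peak, which 68.9% of random lists reached, and 2 a knockout peak, which 16.7% reached, numbers too small to decide. DNA copies of the transcripts, from a construct or cDNA, may be a source, because 0 peaks of either list lay between Ghdc and Stat3 outside the 2 gene bodies. That interval has only 11.7 kb, 10.1% of its length, outside the gene bodies, and exon positions, which would tell the explanations apart, were not used here. STAT5 binding within its own genes alone stays open, as does the same account for the 3 Tert peaks of the wild type.

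Outside the STAT5 genes and mitochondrial DNA, 2 nuclear wild-type peaks shared a position with a knockout peak. Chance placement alone is argued against, as 0.6% of random placements gave as many. The number is 2, however, random positions could fall in unmappable sequence, and the placements did not keep the clustering of the peaks. These peaks were also chosen after the data were seen, so the evidence is weak. Common sites missed near the calling threshold could also leave the lists so different, and the share in the top quartile of wild-type peaks, 0.0% of 290, did not exceed that in the lowest quartile. That bound was a poor choice, because a knockout library too shallow to recover the common sites would give a share near 0 in every quartile, so with 2 shared peaks this explanation cannot be told apart from a difference in binding between the genotypes, which was not tested.

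Peaks beyond the last gene of a chromosome were in the wild-type list alone, while those before the first gene (1 and 2) were not. The shorter knockout list is argued against as the whole account. Scaling the 14 wild-type chromosomes by the number of nuclear peaks gave 9.69 chromosomes with a knockout peak beyond the last gene, and 0 had one. The 9.69 is a rough figure, because some chromosomes held several such peaks and would not drop out in proportion to the length of the list. A lack of high-scoring knockout peaks stays open, since 18 of the 204 nuclear wild-type peaks with a p-value under 0.01 were distal and the same share of the 5 such knockout peaks would be 0.441. That figure leaves out the other distal wild-type peaks, with the authors' p-values from 0.0127 to 0.165. The number they would give among the weaker knockout peaks was not computed, so 0.441 is not the expectation for the whole knockout list. Better recovery of high-copy sequence in the wild-type library may be the source, in view of the 7SL genes and the chromosome 1 cluster, but the knockout list held 1 cluster at such a place that the wild type lacked, beside Gm10800 and Gm10801, so this explanation remains open. Shorter telomeric repeats in knockout cells could also lower such signal, and this was not tested, since chromosome lengths and repeat sequence were not used here.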
